A study of Mus musculus with 15 samples.

How the data were processed

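Poly-A RNA sequencing libraries were made from the left ventricle of female C57BL/6JRj mice, from 1000 ng of total RNA with a RIN above 8, and read as 150 nt paired ends on a NovaSeq 6000, per the labels' protocols. The 15 libraries fall into 3 groups of 5, named Sham, MI and GSK in the sample names. The protocols speak of independent mice, and each library was treated as a biological replicate. Sham replicates 1 and 2 each mix RNA of 2 animals, so their spread is partly averaged. The sample names of GSK replicates 1 and 2 carry the letter G before the animal number, and all other names carry S. The number 5 with the letter S occurs both in a mixed Sham library and in an MI library, and it was not settled whether a single numbering applies.

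The authors deposited FPKM values, fragments per kilobase of gene length scaled by a library total, for 54532 genes, together with the gene length and coordinates. Per the submitters' processing notes, HISAT2, featureCounts from Subread, DESeq2 and R 3.5.1 were used with build mm10; the notes used here give these names without a role or order. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Of the gene identifiers, 54409 (99.8%) occur in GENCODE vM21, 53499 of them at the same coordinates. Coordinates are printed as in the deposited table, on mm10.

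Each FPKM value times the gene length is a whole multiple of a step specific to the library, for 100% of values within 0.01 of a whole number, so the fragments behind each value could be recovered. The libraries held 21.5 M to 26.8 M fragments assigned to genes, and 1 fragment on a gene of 1 kb equals 0.0357 to 0.0478 FPKM. The deposited FPKM are not scaled by these totals. The scaling total equals a median-of-ratios factor times 23.6 M in every library (Pearson r = 1 across the 15 libraries, against 0.611 with the fragment totals). The values are for that reason relative to the median gene of a library, not to its total, and the share taken by mitochondrial or other abundant transcripts does not set their scale.

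The test was fixed before the data were examined. Values were transformed as log2(FPKM + 1), a pseudocount of 1, which understates the change of genes with low values. Genes with at least 1 FPKM in at least 5 of the 15 libraries were kept, which left 12585 genes. A model of group means was fitted to all 15 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean trend), so that the 3 groups share an estimate of the spread. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Every adjusted p of a gene below comes from this limma fit. A count test was not used, because the deposited unit is FPKM.

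A collection of 60 gene lists for pathways, cell types, complexes and quality was fixed at the same time, with 1343 different genes of which 1326 occur in the table. Lists with at least 3 tested members, 57 in all, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera compares the list with all other genes. It was run again with the correlation estimated from the data, and fry was run beside it. Fry's p tests whether the members of a list move, on balance, to one side, without comparing them with other genes. The library shares of mitochondrial transcripts, of the highest genes and similar measures were compared by exact two-sided permutation tests over the 252 assignments of 5 against 5 libraries, the smallest possible p being 0.00794.

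Genes were named by a rule fixed in advance. For MI against Sham and GSK against MI it takes the 8 largest rises and 8 largest falls among called protein-coding genes with a mean of at least 1 FPKM and no overlap between the 5 libraries of either group, and for GSK against Sham the 5 largest each way. Where fewer than 3 genes pass, it takes the 5 of lowest p as not passing. To these it adds a fixed set of 17 genes of the Polycomb system, cardiac stress, lipid metabolism and fibrosis, and up to 4 members of each list described. Of the genes this rule takes, 4 are not reported here and were not replaced. Genes that overlap others on either strand, or that share sequence with paralogs or pseudogenes, are uncertain, since the counting of shared fragments and the strand setting are not known.

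MI against Sham and GSK against MI share the MI libraries, which by itself gives opposite changes. The covariance of both sets of log2 differences was therefore set beside 100 simulations of groups without an effect and beside all 20 ways to divide the MI libraries into parts of 2 and 3 that serve a single comparison each. The simulated groups carried neither an infarction effect nor a treatment effect. The design foresaw resampled residuals for the simulation. A resampling that draws every library once cancels its own noise, so residuals were weighted by Gaussian draws instead, a change made after the output was seen. The overlap of calls between the comparisons with Sham was set beside independent lists and a division of the Sham libraries. It was also set beside lists of the same sizes, taken by limma's statistic, from 20 simulations without an effect, chosen after seeing the data.

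The fit was tested on simulated data made from the real genes' means and spreads with a seeded set of changed genes. For MI against Sham it recovered 59.4%, 89.4% and 98.4% of genes changed 1.5-fold, 2-fold and 4-fold among 12477 genes. For GSK against MI the shares were 55.2%, 89.4% and 98.5% among 12479 genes, and for GSK against Sham 58.2%, 87.9% and 98.5% among 12482 genes. Of the calls made, 4.76%, 3.01% and 4.71% were unchanged genes. The simulation assumes genes that vary independently, which the real libraries do not show. It also gives each gene the same spread in all 3 groups, pooled over them. In the real libraries the median SD, corrected for the small number of libraries, was 0.123 in Sham, 0.233 in MI and 0.189 in GSK. The shares for GSK against MI may therefore not hold.

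The alternatives fixed in advance were another pseudocount, no filter or a stricter filter, quantile normalization, a further median-of-ratios scaling, leaving out mitochondrially encoded genes, fits of 2 groups, robust estimates, library quality weights, the replicate number as a block, leaving out each library in turn, and leaving out the mixed Sham or the G-numbered GSK libraries. Chosen after seeing the data were a covariate for 3 libraries that stand apart, leaving those 3 out, removing each library's trend with gene length, and limma's voom on the recovered fragments. Tables were handled with data.table (version 1.17.8) and figures drawn with Python 3.11.15 and matplotlib 3.10.9. No 2 libraries of a group were copies, since the chi-square per gene between their fragments was at least 14.3 for every pair of replicates.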

Results

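Gene expression was measured by poly-A RNA sequencing in the left ventricle of female mice aged 12 to 18 weeks, 8 days after surgery. In the MI group a coronary artery had been tied off permanently to cause a myocardial infarction, and the Sham group served as the surgical control; both received the vehicle, 20% Captisol. The GSK group received GSK-343 at 20 mg/kg by daily injection into the abdomen, from 6 h after surgery to day 7. GSK-343 inhibits EZH2, the enzyme of Polycomb repressive complex 2 (PRC2) that places the repressive H3K27 methyl mark on histones. GSK hearts were taken as infarcted from the treatment protocol, since the sample names give the compound only. Each group held 5 libraries (n = 5), with 21.5 M to 26.8 M assigned fragments per library, and 12585 genes were tested. The comparisons ask what infarction changes, with lipid metabolism in view, and whether the inhibitor moves it.

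The first principal component held 52.2% of the variance and the second 13.9%. On the first, Sham libraries scored from -39.0 to -28.2, MI libraries from 10.2 to 50.7, and GSK libraries from -6.33 to 20.6. On the second, MI replicate 4 and GSK replicates 3 and 4 stood apart, at -24.5, -26.9 and -26.7, while all other libraries lay between 0.687 and 20.2. Mitochondrially encoded transcripts took 40.6%, 46.4% and 48.7% of the FPKM total in these 3 libraries. The other MI libraries had 23.2% to 27.6%, the other GSK libraries 31.8% to 32.7%, and the Sham libraries 41.2% to 42.2%. As group means the share was 41.6% ± 0.352 in Sham, 29.0% ± 6.74 in MI and 38.3% ± 8.49 in GSK (SD, n = 5). The exact permutation p was 0.00794 for MI against Sham, the smallest the design allows, and 0.143 after adjustment over 18 tests of library quality; for GSK against MI the exact permutation p was 0.111.

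**Figure D1:**
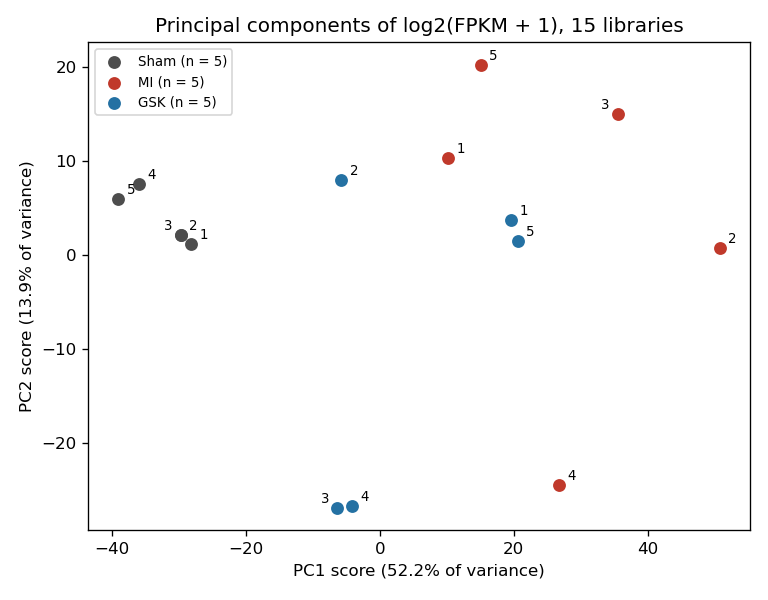
Scores of the 15 libraries on the first (horizontal axis, 52.2% of variance) and second (vertical axis, 13.9%) principal components of log2(FPKM + 1), with colours for the 3 groups and replicate numbers beside the points. MI replicate 4 and GSK replicates 3 and 4 lie at -24.5, -26.9 and -26.7 on the second component, below all other libraries.

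Infarction raised genes of the scar, of macrophages and of dividing cells, and lowered genes of mitochondria and cardiac ion handling. Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037 on mm10), which encodes periostin of activated fibroblasts, rose from 12.3 ± 4.44 FPKM in Sham to 227 ± 113 in MI (SD, n = 5; log2 difference 4.0 ± 0.46 SE, adjusted p = 3.21e-05). Ces1d (ENSMUSG00000056973, chromosome 8, 93166068 to 93197838 on mm10), a carboxylesterase that hydrolyses lipid esters, fell from 85.3 ± 26.0 to 6.99 ± 8.03 FPKM (log2 difference -3.84 ± 0.48 SE, adjusted p = 4.72e-05). In all, 2757 genes were higher and 2758 lower in MI than in Sham. Of these, 491 rose and 304 fell by at least 2-fold. The 5 MI libraries lay wholly above or below the 5 Sham libraries in 3754 genes, 29.8% of those tested against 0.794% by chance.

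The largest rises beside Postn were in Sprr1a (log2 difference 4.51 ± 0.59 SE), a stress-induced cornified envelope protein, and Cthrc1 (4.13 ± 0.87), a secreted protein of activated fibroblasts. Nmrk2, a nicotinamide riboside kinase, rose by 4.12 ± 0.56, and Lox, the lysyl oxidase that crosslinks collagen, by 4.04 ± 0.68. Timp1, an inhibitor of matrix metalloproteinases, rose by 4.02 ± 0.50, the protease inhibitor gene Serpina3n by 3.65 ± 0.50 and Tnc, which encodes tenascin C, by 3.25 ± 0.42. The adjusted p of these 7 genes lay between 4.75e-05 (Timp1) and 0.00162 (Cthrc1). Beside Ces1d, the largest falls were in Cytl1 (-2.61 ± 0.48), the methyltransferase gene Inmt (-2.32 ± 0.37) and Rpl3l (-2.22 ± 0.39), the ribosomal protein form of striated muscle. The mitochondrially encoded mt-Nd3 (-2.18 ± 0.26), Retnla (-2.17 ± 0.37), Myoc (-2.13 ± 0.32) and Efnb3 (-2.11 ± 0.42) followed, with adjusted p from 3.45e-05 (mt-Nd3) to 0.00118 (Efnb3). Timp1, Nmrk2, Tnc and Myoc overlap a gene on the other strand, Ces1d overlaps a predicted gene on its own, and Serpina3n belongs to a family of close paralogs, so their values are uncertain.

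Of 38 tested cell cycle genes, 36 rose and 1 fell in MI (median log2 difference 1.18, camera adjusted p = 4.66e-19). Among them were the mitotic cyclin Ccnb2, from 0.677 ± 0.370 to 6.28 ± 2.01 FPKM, the anaphase activator Cdc20, from 1.02 ± 0.382 to 5.63 ± 2.52, and the topoisomerase Top2a, from 0.487 ± 0.209 to 3.67 ± 1.00. Fibrillar collagens and other matrix genes rose in 30 of 32 (median 1.99, adjusted p = 3.85e-14), including Col8a1 (log2 difference 3.25 ± 0.40 SE), Spp1, which encodes osteopontin (3.09 ± 0.75), and Col1a1 (2.89 ± 0.48). Matrix remodelling and crosslinking enzymes rose in 22 of 29 and fell in 1 (median 0.97, adjusted p = 1.38e-08). Activated fibroblast genes rose in 16 of 20 and fell in 1 (median 1.60, adjusted p = 2.44e-05). Adjusted over the list alone, the counts were the same except for the enzymes, 25 higher and 1 lower. These 4 list calls were lost when the correlation was estimated (adjusted p = 0.528 with an estimated correlation for each).

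Macrophage and monocyte genes rose in 25 of 29 (median 1.30, adjusted p = 5.44e-10). Cd68, a lysosomal protein of macrophages, went from 4.57 ± 0.580 to 28.3 ± 7.83 FPKM, Lgals3, which encodes galectin 3, from 2.87 ± 1.81 to 22.7 ± 17.3, and the cathepsin gene Ctss from 16.2 ± 1.82 to 85.2 ± 52.7. Cytokine, chemokine and inflammasome genes rose in 16 of 21 and fell in 1 (median 0.64, adjusted p = 4.8e-05), with the chemokines Ccl8 (log2 difference 2.96 ± 0.36 SE) and Ccl2 (2.17 ± 0.30) leading. Complement and coagulation genes rose in 14 of 22 and fell in 1 (median 0.99, adjusted p = 8.57e-06), among them Clu (2.06 ± 0.25). Adjusted over the list alone, 25 macrophage, 16 cytokine and 15 complement genes were higher. All 3 list calls were lost when the correlation was estimated (adjusted p = 0.528 with an estimated correlation).

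Genes of the mitochondrion fell together. Enzymes of mitochondrial fatty acid beta-oxidation fell in 20 of 24 (21 adjusted over the list alone; median -0.87, adjusted p = 7.87e-07), among them Acaa2, the thiolase, from 550 ± 52.6 to 255 ± 104 FPKM, and the electron transfer subunit Etfa from 371 ± 23.3 to 170 ± 50.2. Regulators and targets of PPAR and ERR fell in 16 of 22 (16 adjusted over the list alone; median -0.84, adjusted p = 2.44e-05). They included the nuclear receptor Ppara (-1.27 ± 0.17, adjusted p = 8.06e-05), its coactivator Ppargc1a (-1.50 ± 0.28, adjusted p = 0.000656), the uncoupling protein Ucp3 (-2.07 ± 0.60; adjusted p = 0.0747 with the mixed Sham libraries left out) and the thioesterase Acot1 (-1.97 ± 0.22), whose near-identical paralog makes its value uncertain. Genes of the tricarboxylic acid cycle fell in 23 of 27 (23 adjusted over the list alone; median -0.60, adjusted p = 1.85e-07), with Suclg2 (-1.01 ± 0.14) and Sdha (-0.96 ± 0.17). Nuclear-encoded oxidative phosphorylation genes fell in 35 of 49 (44 adjusted over the list alone; median -0.57, or -0.36 under quantile normalization, adjusted p = 2.31e-08), with Cox7a1 (-1.37 ± 0.38) and Ndufa5 (-0.91 ± 0.19). Branched-chain amino acid catabolism fell in 15 of 17 (17 adjusted over the list alone; median -0.85, adjusted p = 6.91e-08), with Ppm1k (-1.40 ± 0.23) and Aldh6a1 (-1.33 ± 0.18). Mitochondrially encoded transcripts fell in 12 of 13 (13 adjusted over the list alone; median -1.16, adjusted p = 2.44e-05), with mt-Nd4l (-2.10 ± 0.42), and the median was -0.46 under quantile normalization; these are the transcripts whose share stood high in MI replicate 4. All 6 calls were lost when the correlation was estimated (adjusted p = 0.528 with an estimated correlation). Cardiomyocyte contractile and Z-disc genes were not called by camera (4 higher and 8 lower of 24, the same adjusted over the list alone; median -0.14, adjusted p = 0.445; adjusted p = 0.828 with an estimated correlation). The libraries hold whole tissue, so a change in cell make-up and a change within cells were not told apart.

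Lipid droplet genes fell in 11 of 20 and rose in 2 (median -0.46, adjusted p = 0.0182), with the droplet proteins Fitm2 (-1.29 ± 0.22) and Plin5 (-1.08 ± 0.24). Adipocyte genes moved with them without being called (2 lower and 1 higher of 7, the same adjusted over the list alone; median -0.86, adjusted p = 0.242; adjusted p = 0.709 with an estimated correlation), and were called lower without Sham replicate 4 (0.0307), the lowest Sham library for both lists. Genes of cholesterol synthesis and uptake rose in 8 of 20 and fell in 2 (median 0.26, adjusted p = 0.0371), with a fall of the synthase Fdft1 (-0.61 ± 0.17). Sphingolipid genes rose in 10 of 22 and fell in 2 (median 0.26, adjusted p = 0.0371), including the kinase Sphk1 (0.87 ± 0.18). Adjusted over the list alone, 2 were higher and 11 lower among lipid droplet genes, 9 and 2 in the cholesterol list, and 10 and 3 in the sphingolipid list. All 3 calls were lost when the correlation was estimated (adjusted p = 0.528 with an estimated correlation) and when the 3 libraries that stand apart were left out (0.0501, 0.125 and 0.0932). The call for cholesterol biosynthesis and uptake was lost in 6 of 22 alternatives, among them without MI replicate 4 or 5 (0.0919 and 0.0569), and that for sphingolipid and ceramide metabolism in 5 of 22, among them without MI replicate 2 or 4 (0.0575 and 0.0654). Cd36, the fatty acid transporter, fell by 0.61 ± 0.19 (adjusted p = 0.0165), and Cpt1b, the carnitine transferase of muscle, by 0.67 ± 0.26 (adjusted p = 0.0452), but the calls were lost in 3 of 26 and 12 of 25 alternatives, with adjusted p up to 0.237 and 0.112. Pparg did not pass (0.18 ± 0.15, adjusted p = 0.339), except with the 2 mixed Sham libraries left out (adjusted p = 0.0142). Camera did not call the lists of fatty acid uptake, fatty acid synthesis, triglyceride synthesis, cholesterol efflux, phospholipids, eicosanoids and ketone bodies (adjusted p from 0.133 to 0.579; adjusted p = 0.528 to 0.828 with an estimated correlation). Fry called 5 of these 7, all but those of fatty acid synthesis and triglyceride synthesis.

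Fetal and stress genes of cardiomyocytes rose in 13 of 16 (13 adjusted over the list alone; median 1.47, camera adjusted p = 0.000243; adjusted p = 0.528 with an estimated correlation). Nppb, which encodes B-type natriuretic peptide, went from 156 ± 132 to 999 ± 554 FPKM (adjusted p = 0.00315), Ankrd1 from 406 ± 249 to 2386 ± 613 (adjusted p = 0.000104), and Ctgf from 32.3 ± 13.7 to 235 ± 143 (adjusted p = 0.0002). Cardiac calcium handling and ion channel genes fell in 17 of 26 and rose in 1, the same counts as adjusted over the list alone (median -0.62, adjusted p = 7.59e-05; adjusted p = 0.528 with an estimated correlation). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell by 1.44 ± 0.25, its inhibitor Pln by 1.33 ± 0.28, and the potassium channel genes Kcnj3 and Kcnip2 by 1.90 ± 0.27 and 1.84 ± 0.34. The atrial peptide gene Nppa (2.51 ± 0.87, adjusted p = 0.0291) and the myosin genes Myh6 (-0.84 ± 0.25, adjusted p = 0.0152) and Myh7 (1.06 ± 0.39, adjusted p = 0.0409) lost their calls in 8, 4 and 14 of 26 alternatives, with adjusted p up to 0.114, 0.311 and 0.12.

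Ezh2 (ENSMUSG00000029687, chromosome 6, 47530139 to 47595341 on mm10) rose from 0.992 ± 0.127 FPKM in Sham to 1.42 ± 0.168 in MI (log2 difference 0.28 ± 0.07 SE, adjusted p = 0.00568). Its call was lost with the 2 mixed Sham libraries left out (adjusted p = 0.0597). The other catalytic subunit gene, Ezh1, fell by 0.27 ± 0.08 (adjusted p = 0.00973; 0.159 with mitochondrially encoded genes left out and totals equalised), and the H3K27 demethylase gene Kdm6b by 0.55 ± 0.10 (adjusted p = 0.000611). Suz12 and Phf1 of PRC2 and the demethylase gene Kdm6a were at adjusted p = 0.049, 0.0381 and 0.0493, lost in 14 of 26, 10 of 26 and 13 of 25 alternatives, with adjusted p up to 0.215, 0.0929 and 0.259. Eed did not pass (-0.12 ± 0.06, adjusted p = 0.125). As lists, PRC2 subunits (1 higher and 4 lower of 10, the same adjusted over the list alone; median -0.15, adjusted p = 0.313) and canonical Polycomb target genes (4 higher and 6 lower of 15, the same adjusted over the list alone; adjusted p = 0.853) were not called by camera, while fry called the PRC2 subunits lower (adjusted p = 0.00488). With mitochondrially encoded genes left out and totals equalised, the PRC2 median was -0.07. With an estimated correlation camera gave adjusted p = 0.528 for PRC2 subunits and 0.868 for target genes. In the target list the median (0.02) and mean (0.13) were above 0 while camera's direction was down. The target genes Gdf6 (2.69 ± 0.43) and Sox9 (1.13 ± 0.22) rose, and Cdkn1c (-1.05 ± 0.14) and Tbx5 (-0.86 ± 0.20) fell.

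In all, camera called 26 of 57 lists between MI and Sham at the preset correlation, 17 higher and 9 lower; fry called 36, of which 25 were shared, and camera with an estimated correlation called 0. The division of calls into higher and lower depended on the scaling. It was 2757 to 2758, or 50.0% higher, as deposited, and 3314 to 1897, or 63.6% higher, once mitochondrially encoded genes were left out and totals equalised, which moved the median of all genes from -0.02 to 0.06 on the log2 scale. Among genes named for the lists, Ezh2, Top2a, Cdc20, Ctss, Ccl2, Spp1, Ppargc1a, Ucp3, Sdha, Ppm1k, Aldh6a1, Fitm2, Fdft1, Sphk1, Cpt1b, Ctgf, Atp2a2, Pln, Kcnj3, Cdkn1c, Kdm6b, Nppa, Myh6 and Myh7 overlap other annotated genes, which makes their values uncertain.

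**Figure D2:**
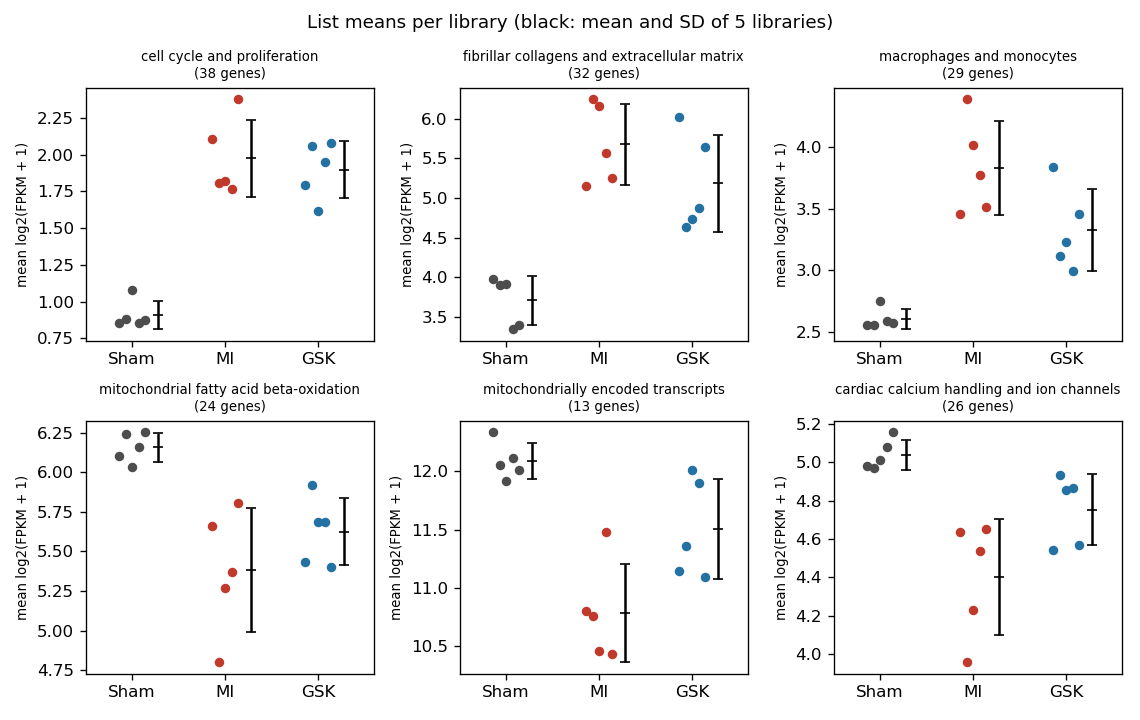
Mean log2(FPKM + 1) of the tested members of 6 gene lists (vertical axes, which do not start at 0) in each of the 15 libraries, by group (horizontal axes); black marks give the mean and SD of 5 libraries. In the cell cycle and macrophage panels the GSK mean lies between Sham and MI. In the cell cycle panel it lies near MI (1.90, against 0.910 in Sham and 1.97 in MI), with a median log2 difference of -0.05. GSK replicate 3 (1.61) lies there below all MI libraries. The difference in position between both lists was not told apart from chance (exact two-sided permutation p = 0.357).

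Between GSK and MI no single gene passed the test. Camera called 22 of 57 lists at its preset correlation, but 0 with an estimated correlation (lowest adjusted p = 0.633 with an estimated correlation), and fry called 0 without a covariate (lowest adjusted p = 0.076). With limma, 0 genes were called higher and 0 lower, the smallest adjusted p being 0.0536, although 2638 genes had an unadjusted p under 0.05 against 629 expected by chance. Of these, 1364 were higher and 1274 lower in GSK, and 253 genes (2.01%, against 0.794% by chance) separated the 5 GSK from the 5 MI libraries. The fit shares its estimate of the spread with Sham, whose libraries varied less. In the limma fit of GSK and MI alone, 1878 genes had an unadjusted p under 0.05 and 0 were called. Genes vary together, so how far a count can move from 629 by chance is not known. Limma's voom on the recovered fragments, added after seeing the data, called 2 genes higher and 0 lower, with 2670 unadjusted. Ezh2 was at 1.30 ± 0.0817 FPKM in GSK and 1.42 ± 0.168 in MI (SD, n = 5; log2 difference -0.07 ± 0.07 SE, adjusted p = 0.577), so its transcript level did not mark the treatment.

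The protein-coding genes of lowest p in each direction, taken by the naming rule, were the following, and none of them passed. Ctf1 (ENSMUSG00000042340, chromosome 7, 127712736 to 127718192 on mm10), which encodes the cytokine cardiotrophin 1, stood at 1.52 ± 0.223 FPKM in MI and 3.05 ± 0.596 in GSK (log2 difference 0.68 ± 0.10 SE, adjusted p = 0.0536). Sham libraries had 3.75 ± 0.492. Tnrc6b (0.43 ± 0.07) and the transcription factor gene Zbtb20 (0.76 ± 0.12) had the same adjusted p, and the phospholipid enzyme gene Chpt1 (0.54 ± 0.10) and the adrenergic receptor gene Adra1a (0.81 ± 0.15) stood at 0.0751. In the other direction Socs3 (ENSMUSG00000053113, chromosome 11, 117966079 to 117970047 on mm10), an inhibitor of cytokine signalling, had 8.93 ± 2.95 FPKM in MI and 3.46 ± 1.18 in GSK (-1.14 ± 0.20, adjusted p = 0.0751), against 2.35 ± 0.145 in Sham. Ipo4 (-0.50 ± 0.09), Smarcb1 (-0.35 ± 0.06), Galns (-0.71 ± 0.13) and the deacetylase gene Hdac6 (-0.36 ± 0.07) had that adjusted p too. Ctf1, Tnrc6b, Zbtb20 and Socs3 passed in 6 of 25, 7 of 25, 7 of 26 and 5 of 26 alternatives, with an adjusted p of 0.0097 without MI replicate 1. Chpt1 passed in 4 of 26, Ipo4 and Smarcb1 in 4 of 25, and Adra1a, Galns and Hdac6 in 3 of 25. Ctf1, Tnrc6b, Zbtb20, Chpt1, Ipo4 and Galns overlap other genes.

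**Figure D3:**
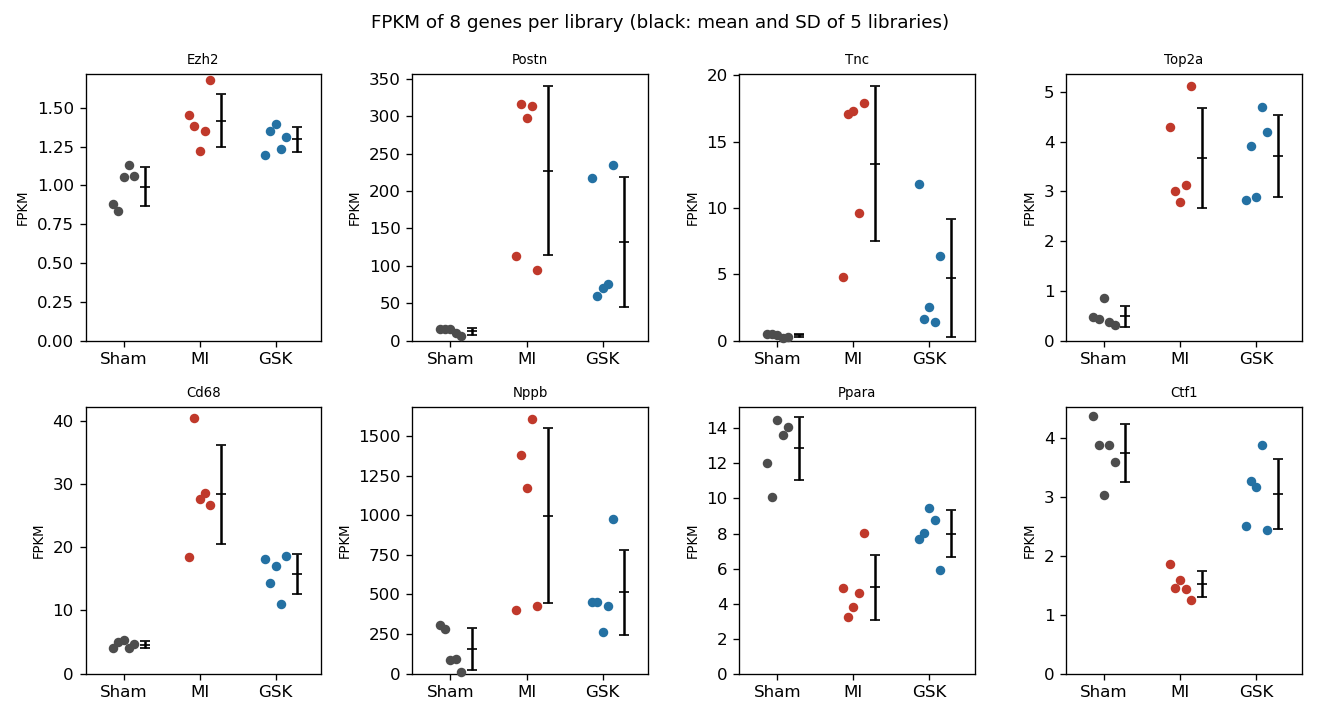
FPKM of 8 genes (vertical axes from 0) in each library of the 3 groups (horizontal axes); black marks give the mean and SD of 5 libraries. Top2a stood at 3.67 ± 1.00 in MI and 3.71 ± 0.821 in GSK, and Ctf1 at 1.52 ± 0.223 and 3.05 ± 0.596, a difference that did not pass (adjusted p = 0.0536).

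Of the 22 lists that camera called between GSK and MI, 9 were higher and 13 lower. None of their members passed over all genes, and the calls ended in both other tests, so the list differences below rest on the preset correlation. With the split of the 3 libraries that stand apart as a covariate, chosen after seeing the data, fry called 1 list, mitochondrially encoded transcripts, higher (adjusted p = 0.000436).

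Lists of cardiomyocyte metabolism and ion handling were higher in GSK. Branched-chain amino acid catabolism had a median log2 difference of 0.40 (adjusted p = 8.72e-07), with Ppm1k (0.77 ± 0.23 SE) and Dbt (0.67 ± 0.16). Mitochondrially encoded transcripts had a median of 0.75 (adjusted p = 1.09e-05), with mt-Nd3 at 105 ± 21 FPKM in MI and 285 ± 120 in GSK; GSK replicates 3 and 4 had the highest mitochondrial shares of all libraries, and under quantile normalization the median was 0.22. Calcium handling and ion channel genes had a median of 0.30 (adjusted p = 6.94e-05), with the pacemaker channel gene Hcn4 (1.01 ± 0.32) and Kcnip2 (1.01 ± 0.34). Tricarboxylic acid cycle genes had 0.22 (adjusted p = 0.000846), regulators and targets of PPAR and ERR 0.36 (adjusted p = 0.00262), with Ppara (0.64 ± 0.17) and, in the other direction, Angptl4 (-0.90 ± 0.58), and fatty acid beta-oxidation 0.28 (adjusted p = 0.00287), with Cpt2 (0.52 ± 0.25) and Acad11 (0.48 ± 0.18). Adjusted over the list alone, 9 branched-chain, 9 mitochondrially encoded, 11 ion handling and 2 PPAR genes were higher, and 0 in the other 2 lists (limma; 0 of all genes called, 2638 at unadjusted p under 0.05). For these 6 lists adjusted p = 0.633 to 0.661 with an estimated correlation. The beta-oxidation and tricarboxylic acid cycle calls were lost without MI replicate 2 (0.135 and 0.12), and with the 3 libraries that stand apart left out those of beta-oxidation and PPAR were lost (0.0535 and 0.147). The difference of list means moved then from 0.24 to 0.20 for beta-oxidation and from 0.28 to 0.08 for PPAR. Nuclear-encoded oxidative phosphorylation was not called (median 0.09, adjusted p = 0.105), but was called higher in 8 of 22 alternatives, among them without MI replicate 1 or 5 or GSK replicate 3 or 4, with adjusted p down to 9.61e-05. Among MI libraries Hcn4 was highest in replicate 1 (2.83 FPKM, others up to 1.18), which also had the highest mean of the atrial list (4.88). The difference in Hcn4 can therefore not be told apart from atrial tissue.

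Of the other lipid lists, camera called that of peroxisomal lipid metabolism higher between GSK and MI (median 0.22, adjusted p = 0.0194; adjusted p = 0.661 with an estimated correlation), a call lost without MI replicate 2 (0.26) or GSK replicate 2 (0.0712), with 0 of 18 members passing adjusted over the list alone (limma). The rest were called by neither camera nor fry. Lipid droplet genes had a median of 0.13 (camera adjusted p = 0.214; called higher at 0.0499 without MI replicate 1), and cholesterol synthesis and uptake -0.12 (adjusted p = 0.212). Sphingolipid genes had a median of -0.06 (adjusted p = 0.105; called lower without MI replicate 1 or 5 or GSK replicate 3, down to 0.0342). In each of these 3 lists 0 members passed adjusted over the list alone (limma). The lists of fatty acid uptake, fatty acid synthesis, triglyceride synthesis, cholesterol efflux, phospholipids, eicosanoids and ketone bodies had adjusted p from 0.231 to 0.979. In these, 1 efflux gene was lower, 1 phospholipid gene higher and 1 lower, and 1 ketone body gene higher when adjusted over the list alone. For these lists and the 3 above adjusted p = 0.633 to 0.987 with an estimated correlation.

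Lists of inflammatory cells, matrix and translation were lower in GSK. Macrophage and monocyte genes had a median of -0.51 (adjusted p = 8.24e-07), with Chil3 at 3.85 ± 4.39 FPKM in MI and 0.378 ± 0.207 in GSK, Arg1 at 3.89 ± 2.47 and 1.03 ± 1.38, and Cd68 at 28.3 ± 7.83 and 15.8 ± 3.15. Neutrophil genes had -0.81 (adjusted p = 0.00469), with the calgranulins S100a9 (-0.95 ± 0.36) and S100a8 (-0.85 ± 0.25). Fibrillar collagens and matrix genes had -0.47 (adjusted p = 8.8e-05), with Tnc (-1.51 ± 0.42) and Spp1 (-0.90 ± 0.75). Cytosolic ribosomal proteins had -0.30 (adjusted p = 1.1e-12), with Rpl3 (-0.62 ± 0.14) and Rps16 (-0.51 ± 0.19), genes whose pseudogenes make single values uncertain. In the ribosomal list GSK replicates 3 and 4 had means of 6.38 and 6.25, while the other GSK libraries (6.74 to 6.88) lay within the range of MI (6.73 to 7.11). Fetal and stress genes had -0.58 (adjusted p = 0.00208), with Fhl1 (-1.27 ± 0.32), Ankrd2 (-1.27 ± 0.35) and Myl4 in the other direction (1.58 ± 0.98), and epicardial and mesothelial genes -0.45 (adjusted p = 0.00716), with Aldh1a2 (-1.73 ± 0.35) and Msln (-0.87 ± 0.52). Among MI libraries Myl4 ran from 1.09 to 90.4 FPKM and the atrial light chain gene Myl7 from 3.35 to 402. Both were highest in MI replicate 1 and lowest in MI replicates 3 and 5, so the difference in Myl4 cannot be told apart from atrial tissue. Adjusted over the list alone, 14 macrophage, 5 neutrophil, 0 matrix, 2 ribosomal, 3 fetal and 2 epicardial genes were lower. For all 6 lists adjusted p = 0.633 with an estimated correlation. With the 3 libraries that stand apart left out, camera still called all 6 lower, the highest adjusted p being that of fetal and stress genes of cardiomyocytes (0.0305), but the difference of list means moved from -0.31 to -0.16 for ribosomal, from -0.49 to -0.27 for matrix, from -0.44 to -0.16 for fetal and from -0.51 to -0.33 for epicardial genes. Activated fibroblast genes were not called (camera adjusted p = 0.138), except in 3 of 22 alternatives (without MI replicate 1 or 5 or GSK replicate 1, down to 0.00919). Their difference of list means was -0.25, and -0.03 with the 3 libraries left out. TGF-beta genes were not called either (camera adjusted p = 0.105), except without MI replicate 1 (0.0253) or GSK replicate 1 (0.0492).

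Interferon response genes were higher in GSK (median 0.16, adjusted p = 0.00716; adjusted p = 0.769 with an estimated correlation), with 0 of 36 members passing over all genes or adjusted over the list alone (limma). Iigp1 stood at 8.58 ± 4.21 FPKM in MI and 17.0 ± 4.23 in GSK, Rsad2 at 5.85 ± 3.43 and 8.00 ± 1.54, and Gbp7 at 3.18 ± 1.02 and 4.70 ± 0.481. The call was lost without MI replicate 2, 4 or 5 (0.12, 0.25 and 0.209 in the interferon response list), without GSK replicate 1 or 5 (0.0613 and 0.0877) and without both G-numbered GSK libraries (0.0705). H3K27 demethylases with H3K4 and H3K36 methyltransferases were higher (median 0.13, adjusted p = 0.00612; adjusted p = 0.633 with an estimated correlation), led by the H3K4 enzyme gene Kmt2c (0.41 ± 0.08, adjusted p = 0.0751) and Ash1l (0.29 ± 0.11), with 3 members higher adjusted over the list alone. That call was lost once trends with gene length were removed (0.393). Among these genes Kdm6a (0.25 ± 0.12) and Kdm6b (0.13 ± 0.10) did not pass. Cell cycle genes (median -0.05, adjusted p = 0.0805), canonical Polycomb targets (0.01, adjusted p = 0.569) and PRC2 subunits (0.02, adjusted p = 0.345) were not called. For the cell cycle list, leaving out MI replicate 2, 3 or 4 or GSK replicate 2, 4 or 5 each gave a call of lower expression, with adjusted p from 0.00652 to 0.023.

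The number of genes called between GSK and MI depended on single libraries. It was 204 higher and 188 lower without MI replicate 1, 154 and 134 without GSK replicate 5, 19 and 7 without MI replicate 4, and 6 and 1 without GSK replicate 1; without any other library it was 0. With the 3 libraries that stand apart left out it was 0, with 1231 genes at an unadjusted p under 0.05, and with their split as a covariate, chosen after seeing the data, 50 higher and 16 lower.

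Across genes, the differences between GSK and MI ran against those between MI and Sham. Of genes that rose with infarction 90.7% were lower in GSK than in MI (median log2 difference -0.21), and of genes that fell 94.8% were higher (median 0.22). At an unadjusted p under 0.05, 984 of the risen genes were lower in GSK and 6 higher, and 1081 of the fallen genes were higher and 1 lower. Both comparisons use the MI libraries, which alone gives opposite signs, and more so among genes chosen by their MI values, for which no value without an effect was computed. Over all 12585 genes 77.8% were opposite in sign, against a mean of 73.9% (range 47.1% to 88.6%, which holds the observed share) in simulations without an effect and 69.0% with the MI libraries divided as below. The covariance of the log2 differences was -0.112, against a mean of -0.0219 (range -0.0786 to 0.000403) in 100 simulations without an effect, a difference of -0.0898. These simulations leave out the infarction effect too. They do not show what covariance chance gives where MI differs from Sham and GSK does not differ from MI. The observed value lying outside their range is therefore no evidence of a treatment effect. With the MI libraries divided so that none was shared, the 20 covariances averaged -0.0919 and ranged from -0.129 to -0.0318. These divisions reuse the same 15 libraries and are not independent, and no value without an effect was computed for them. The correlation across genes, which are not independent replicates, was -0.785, within the simulated range of -0.937 to 0.0384 (mean -0.621), and averaged -0.569 over the divided libraries.

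GSK hearts still differed widely from Sham, among others in matrix, cell cycle, macrophage and oxidative phosphorylation genes. Postn stood at 132 ± 86.8 FPKM against 12.3 ± 4.44 in Sham (log2 difference 3.15 ± 0.46 SE, adjusted p = 0.000686), Lox was higher by 2.83 ± 0.68, Col8a1 by 2.61 ± 0.40 and Wisp2, a matricellular protein gene, by 2.60 ± 0.49. Cthrc1 was higher by 3.15 ± 0.87 (adjusted p = 0.0237), a call lost in 8 of 26 alternatives with adjusted p up to 0.143. Retnla (-2.01 ± 0.37), Ces1d (-1.95 ± 0.48), the galectin gene Lgals4 (-1.66 ± 0.30) and Tbc1d10c (-1.51 ± 0.25) were the largest falls of those named by the rule, with adjusted p from 0.00162 (Tbc1d10c) to 0.0139 (Ces1d). In all, 1354 genes were higher and 954 lower, 162 and 74 of them by at least 2-fold.

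Cell cycle genes rose in 33 of 38 (35 adjusted over the list alone; median 1.01, adjusted p = 5.52e-29), with Ccnb2 (2.11 ± 0.23), Ube2c (1.67 ± 0.19) and Top2a (1.66 ± 0.15). Fibrillar collagens and matrix genes rose in 28 of 32 (30 adjusted over the list alone; median 1.36, adjusted p = 1.36e-17), and Col1a1 by 2.05 ± 0.48. Macrophage genes rose in 16 of 29 (20 adjusted over the list alone; median 0.74, adjusted p = 5.62e-09), with Cd68 (1.57 ± 0.17) and the chemokine receptor gene Cx3cr1 (1.43 ± 0.25), which overlaps other genes. Interferon response genes rose in 13 of 36 (19 adjusted over the list alone; median 0.47, adjusted p = 6.71e-08), with Ifi27l2a (0.98 ± 0.22, adjusted p = 0.00889), Irf7 (1.06 ± 0.29, adjusted p = 0.0215) and Ifit3 (0.96 ± 0.26, adjusted p = 0.0225). The calls of Irf7 and Ifit3 were lost in 6 and 7 of 26 alternatives, with adjusted p up to 0.0846 and 0.0648, and that of Ifi27l2a in 1 (0.0578). For all 4 lists adjusted p = 0.57 with an estimated correlation.

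Fatty acid beta-oxidation genes fell in 11 of 24 (16 adjusted over the list alone; median -0.53, adjusted p = 1.14e-06), with Etfa (-0.78 ± 0.19, adjusted p = 0.0115; 0.0504 under quantile normalization), and nuclear-encoded oxidative phosphorylation genes in 12 of 49 (34 adjusted over the list alone; median -0.48, or -0.25 under quantile normalization, adjusted p = 1.62e-10), with Cox7a1 (-1.23 ± 0.38, adjusted p = 0.0352), lost in 14 of 26 alternatives with adjusted p up to 0.113. Lipid droplet genes fell in 5 of 20 and rose in 1 (6 and 1 adjusted over the list alone; median -0.30, or -0.18 with mitochondrially encoded genes left out and totals equalised, adjusted p = 0.0197), with the perilipin gene Plin4 (-0.76 ± 0.11, adjusted p = 0.000634). For these 3 lists adjusted p = 0.57 with an estimated correlation. Adipocyte genes were not called by camera (adjusted p = 0.169), but were called lower without Sham replicate 4 (0.00531) or GSK replicate 3 (0.0331). Cholesterol synthesis and uptake was not called (5 of 20 higher, and 5 higher and 1 lower adjusted over the list alone; median 0.13, adjusted p = 0.0603). It was called higher in 5 of 22 alternatives, among them without Sham replicate 5, MI replicate 4, or GSK replicate 1 or 5, with adjusted p down to 0.0372, and with the replicate block (0.0457). Nor were sphingolipid genes called by camera (7 of 22 higher, 8 adjusted over the list alone; median 0.18, adjusted p = 0.0823), though fry called them (0.0402). The lists of fatty acid uptake, fatty acid synthesis, triglyceride synthesis, cholesterol efflux, phospholipids, eicosanoids and ketone bodies had camera adjusted p from 0.107 to 0.544. Of them fry called those of efflux (0.0421), phospholipids (0.0402) and eicosanoids (0.0186). With the replicate block fry called 1 list, which camera called too, so these fry calls and that of sphingolipid genes were lost. Mitochondrially encoded transcripts fell in 3 of 13 (3 adjusted over the list alone; median -0.43, adjusted p = 0.0076; adjusted p = 0.574 with an estimated correlation), with mt-Co2 (-1.44 ± 0.28; adjusted p = 0.0806 under quantile normalization) and mt-Atp8 (-1.21 ± 0.30; adjusted p = 0.0698 with the mixed Sham libraries left out). That list call was lost under quantile normalization (0.176), without the G-numbered GSK libraries (0.127) and with length trends removed (0.0503). Ezh2 did not pass between GSK and Sham (0.21 ± 0.07, adjusted p = 0.0556), but did in 5 of 25 alternatives, with adjusted p down to 0.0197 with mitochondrially encoded genes left out and totals equalised. Camera called 18 of 57 lists, fry 17, with 12 shared, and camera with an estimated correlation 0.

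Calls were shared between the comparisons with Sham for 1253 higher and 878 lower genes, against 297 and 209 for independent lists. In 20 simulations without an effect, lists of the same sizes shared 656 higher (255 to 1088) and 478 lower genes (169 to 762) on average through the common Sham libraries. With the Sham libraries divided the means were 428 and 180, against 73.1 and 29.1 for independent lists in those fits. The counts of GSK against Sham depended on single libraries, the lowest being 773 higher and 412 lower without GSK replicate 5, followed by 850 and 460 without Sham replicate 4, 880 and 482 without GSK replicate 1, and, for lower genes, 456 without Sham replicate 5 and 610 without Sham replicate 3. With mitochondrially encoded genes left out and totals equalised, the division was 1960 higher to 425 lower, or 82.2% higher against 58.7% as deposited, and the median of all genes moved from -0.02 to 0.09 on the log2 scale.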

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

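The tests in this part, of atrial tissue and of short transcripts, were chosen after the 3 libraries had been seen to stand apart. A first atrial test took the distance of each library's atrial list mean from the others of its group. It gave 0.895 SD for MI replicate 4 and -0.387 and -0.42 SD for GSK replicates 3 and 4, and did not decide. The atrial test below replaced it after that result was seen.

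For 115 genes, 24 list means and 2 library shares, the highest or lowest library of each group of 5 was compared with the next. In 35 of 423 groups the gap took more than 0.71 of the group's range, Dixon's 95% limit. For normally distributed values chance gives about 1 in 20, or 21.15. The gene values were FPKM without log transformation, for which that rate need not hold, so 35 against 21.15 does not show an excess. Of these, 12 lay in Sham, 13 in MI and 10 in GSK.

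Among Sham libraries, replicate 3 stood out with Myoc at 12.96 FPKM (others up to 9.40), Ccl8 at 8.13 (others up to 2.82), Irf7 at 4.63 (others up to 3.40), and list means on the log2 scale of 1.08 for cell cycle genes and 2.75 for macrophage genes. Sham replicate 5 stood out with Atp2a2 at 3170.4 FPKM, Pln at 709 and a mean of 3.84 for fetal and stress genes, against at least 4.84 in the others. Sham replicate 1 had Ppargc1a at 50.5 FPKM (others up to 20.46) and Sphk1 at 0.925. Sham replicate 4 had mt-Nd3 at 723 FPKM, and Sham replicate 2 had Cx3cr1 at 2.39. Sham replicates 1 and 2 each mix 2 animals; the labels name 1 animal for each of the others.

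Among MI libraries, replicate 2 stood out with Spp1 at 197 FPKM (others up to 31.0), Sprr1a at 115 (others up to 34.4), Chil3 at 11.5 (others up to 3.37) and Ankrd2 at 9.90. MI replicate 1 had Ces1d at 21.1 FPKM (others up to 4.65), Ucp3 at 23.5 (others up to 5.33), Hcn4 at 2.83 and Hdac6 at 3.92, the last below the others. Among GSK libraries, replicate 1 stood out with Eln at 369.8 FPKM (others up to 54.5), Myl4 at 97.4, S100a9 at 4.89 and S100a8 at 2.37. GSK replicate 5 had Nppb at 974 FPKM (others up to 454), Ankrd1 at 2969.8 and Nmrk2 at 78.8 (others up to 21.8). GSK replicate 2 had Myh6 at 3101.7 FPKM, Sdha at 398 and a mean of 8.30 for nuclear-encoded oxidative phosphorylation genes.

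MI replicate 4 stood out with Suz12 at 7.59 FPKM, Cdkn1c at 2.13, mt-Atp8 at 21.1, a mitochondrial share of 40.6% of FPKM and a share of 42.7% for its 10 highest genes, against at most 30.4% in the other MI libraries. With GSK replicates 3 and 4 it stands apart on the second principal component, and these 3 libraries have the lowest medians of short relative to long genes (-0.34, -0.40 and -0.49 on the log2 scale; others -0.28 or above) and the lowest shares of miRNA genes (0.394% to 0.899%; others at least 1.54%), as a loss of short transcripts would give. Removing each library's trend with gene length left the lowest correlation of deviations between MI replicate 4 and these GSK libraries at 0.465 (0.486 before), so such a trend is argued against as the whole cause, though not as a part of it. More atrial tissue is argued against as the whole cause, since 4 of the 12 other libraries (Sham replicates 3 and 4, MI replicate 1 and GSK replicate 1) had higher means of the atrial list (4.88 to 5.32, against 3.91 to 4.43 in the 3) and scored 2.12 or above on the second component (SD of the 12 scores 6.11), where the 3 lay at -24.5 or below. A difference in library preparation or in the piece of ventricle taken stays open, since the labels give neither, and no biological explanation was tested.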

How the results depend on the processing

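The covariate for the 3 libraries that stand apart, their removal, the removal of length trends and voom were alternatives chosen after the result was seen; all others were fixed in advance.

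Between MI and Sham, 2757 genes were called higher and 2758 lower, and the stricter filter, which tests 6855 genes, left 1508 and 1762, fewer genes being tested; in the other settings both counts stayed within 1.5 times. Between GSK and Sham, with 1354 and 954, the stricter filter left 755 and 629. Leaving out the mixed Sham libraries gave 779 and 463, and leaving out the G-numbered GSK libraries 792 and 600, with fewer samples in each. Library quality weights gave 2192 and 2026. The count of lower genes alone moved to 592 without a filter and to 535 with the replicate block. It moved to 425 with mitochondrially encoded genes left out and totals equalised (424 of them shared with the 954), and to 1634 in the fit of 2 groups. The cause of these moves was not tested. Between GSK and MI limma called 0 and 0 (2638 at an unadjusted p under 0.05), a pseudocount of 0.1 gave 3 higher, voom 2 higher, and the covariate 50 higher and 16 lower; the cause was not tested.

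With each library left out in turn, 2402 to 2773 genes were higher and 2265 to 2909 lower between MI and Sham. Between GSK and Sham the range was 773 to 1355 higher and 412 to 1131 lower, the counts moving by over 1.5 times without GSK replicate 5 (773 and 412), GSK replicate 1 (880 and 482), Sham replicate 4 (850 and 460), Sham replicate 5 (456 lower) and Sham replicate 3 (610 lower). Between GSK and MI it was 0 to 204 higher and 0 to 188 lower, with calls without MI replicate 1 (204 and 188), GSK replicate 5 (154 and 134), MI replicate 4 (19 and 7) and GSK replicate 1 (6 and 1).

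The replicate numbers did not pair the libraries: of 15 same-numbered pairs 2 had a correlation of deviations over 0.1 (range -0.41 to 0.49), and 2 of 15 libraries correlated best with their own number. With the replicate block 2549 and 2472 genes were called between MI and Sham, 0 and 0 between GSK and MI (2361 at an unadjusted p under 0.05), and 924 and 535 between GSK and Sham. Camera called 26, 22 and 19 lists with the block, and fry 36, 0 and 1.

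Of 2959 values of the named genes under alternatives in each comparison, 2817 (MI against Sham), 2779 (GSK against MI) and 2577 (GSK against Sham) kept direction and side of the threshold; 120, 0 and 273 lost a call, 11, 93 and 67 gained one, and 11, 87 and 42 changed sign without a call. Of 1482 list values in each, 1378, 1282 and 1349 kept both. A single list turned: cytosolic ribosomal proteins, lower in GSK than in Sham as deposited (adjusted p = 0.698), were called higher with the 3 libraries left out (adjusted p = 0.0075) and lower without the G-numbered GSK libraries (adjusted p = 0.00792; range over all alternatives 0.0075 to 0.999), and the cause was not tested. The covariance of MI and GSK changes was -0.112, and -0.0919 with divided MI libraries. Depth limits low genes: 1 fragment on 1 kb equals 0.0357 to 0.0478 FPKM, and Ezh2 rests on 130 to 289 fragments per library.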

Other observations

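Of the tests in this part, those of the splits of GSK and MI libraries, the covariate, the spread between hearts, the length trends and the share of infarcted tissue were chosen after the result was seen.

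Beyond the lists described above, infarction raised genes of cytosolic ribosomal proteins in 17 of 53 (15 adjusted over the list alone; median log2 difference 0.26, or 0.39 under quantile normalization, camera adjusted p = 0.000283; adjusted p = 0.639 with an estimated correlation). Rpl3 rose by 1.27 ± 0.14 SE and Rps12 by 0.78 ± 0.17; named pseudogenes of both (2 and 23) and overlapping genes make these values uncertain. Genes of the epicardium and mesothelium rose in 6 of 11 (7 adjusted over the list alone; median 0.63, adjusted p = 0.0153), neutrophil genes in 3 of 6 (3 adjusted over the list alone; median 0.98, adjusted p = 0.0151) and immediate early genes, which dissection can raise too, in 8 of 23 with 1 lower (8 and 1 adjusted over the list alone; median 0.57, adjusted p = 0.00794), each at adjusted p = 0.528 with an estimated correlation. Interferon response genes rose in 10 of 36 and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.0153; adjusted p = 0.709 with an estimated correlation), a call lost without MI replicate 1 (0.235), without MI replicate 3 (0.0801) and with fry (0.171). Apoptosis genes rose in 10 of 22 with 2 lower (median 0.27, adjusted p = 0.0167) and TGF-beta genes in 11 of 25 with 3 lower (0.35, adjusted p = 0.0293, lost in 4 of 22 alternatives of camera, such as without MI replicate 2 at 0.0502, up to 0.054), and peroxisomal lipid genes fell in 9 of 18 with 1 higher (-0.31, adjusted p = 0.0153), at adjusted p = 0.528, 0.528 and 0.567 with an estimated correlation. GSK differed from Sham in the same direction as MI for matrix enzymes (17 of 29 higher; median 0.68, adjusted p = 5.53e-09), myofibroblast genes (12 of 20; 1.38, adjusted p = 4.86e-07), complement genes (9 of 22; 0.62, adjusted p = 1.46e-05) and cytokine genes (7 of 21 with 1 lower; 0.42, adjusted p = 0.00084). It was lower than Sham for genes of the TCA cycle (8 of 27; -0.38, or -0.19 under quantile normalization and -0.25 with mitochondrially encoded genes left out and totals equalised; adjusted p = 8.42e-07), branched-chain amino acid catabolism (8 of 17; -0.46, adjusted p = 3.87e-06) and PPAR targets (9 of 22; -0.60, adjusted p = 8.08e-05), all 7 at adjusted p = 0.57 with an estimated correlation.

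Between GSK and MI, camera also called cytokine and chemokine genes lower (median -0.34, adjusted p = 0.000846), with Ccl2 at -1.19 ± 0.30 SE (adjusted p = 0.1), and complement genes (-0.33, adjusted p = 0.000846), matrix enzymes (-0.39, adjusted p = 0.000323), immediate early genes (-0.30, adjusted p = 0.00287) and glycolysis genes (-0.26, adjusted p = 0.0114), each at adjusted p = 0.633 with an estimated correlation. Adjusted over the list alone, 3, 2, 0, 1 and 5 of their genes were lower, and 1 glycolysis gene higher. Over all genes limma called 0, with 2638 at an unadjusted p under 0.05 and 2 called by voom, and fry called 0 of 57 lists without a covariate (lowest adjusted p = 0.076). With the 3 libraries that stand apart left out, the difference of list means moved from -0.18 to -0.09 for glycolysis and from -0.39 to -0.21 for matrix enzymes. The glycolysis call was lost without MI replicate 5 (0.121) and the immediate early call without the G-numbered GSK libraries (0.0646). Dendritic cell genes (-0.34, adjusted p = 0.026) and red blood cell genes (-0.77, adjusted p = 0.0238) were lower, calls lost in 6 and 4 of 22 alternatives of camera (up to 0.142 without MI replicate 3, and 0.217 with the 3 libraries that stand apart left out), both at adjusted p = 0.633 with an estimated correlation.

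Chance is argued against, though not excluded, for the counts of genes against Sham. Of 100 splits of the 10 libraries, 1, the real one, gave as many as the 5515 between MI and Sham (highest other 2). Likewise 1 gave as many as the 2308 between GSK and Sham (highest other 3). The real split is among the 100, so 1 is the lowest possible result. All other splits mix both groups, which widens the spread and lowers their counts. For GSK and MI the splits cannot test chance, since limma called 0 genes (2638 at an unadjusted p under 0.05; voom 2) and each of 100 splits gives at least 0. The highest other split called 1369 genes, with MI replicates 1 and 5 and GSK replicates 2, 3 and 4 against the rest, whose scores on the first principal component do not overlap (-6.33 to 15.1 against 19.6 to 50.7). That split was picked for its count, and the first component holds 52.2% of the variance, so the lack of overlap is no separate evidence. The 1369 calls describe a difference among these 10 libraries that crosses the groups. Leaving out 1 library also gave calls between GSK and MI: 204 higher and 188 lower without MI replicate 1, 154 and 134 without GSK replicate 5, 19 and 7 without MI replicate 4, and 6 and 1 without GSK replicate 1.

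That no gene passed between GSK and MI may come from variation between infarcted hearts. The median SD between libraries, corrected for the small number of libraries, was 1.54 times that of Sham in GSK and 1.90 times in MI. It was 1.26 and 1.74 times without the 3 libraries that stand apart. Whether those 3 libraries hide differences cannot be told apart from chance. With their split as a covariate 66 genes passed. Of the 50 sets of 1 MI and 2 GSK libraries, their own included, 8 gave as many or more, up to 2107. With the 3 left out 0 passed (1231 at an unadjusted p under 0.05). The mixing of animals in Sham replicates 1 and 2 does not account for the ratio, which was 1.60 for GSK and 1.97 for MI against the unmixed Sham libraries.

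GSK hearts may lie part of the way between MI and Sham because the compound changed the response, because less infarcted tissue was in the libraries, or by chance. The shared MI libraries are argued against as the whole cause, since the covariance stayed negative in each of 20 divisions of them, the highest being -0.0318. Length trends are argued against in the same way, the highest covariance over these divisions being -0.0325 after their removal. The divisions reuse the same 15 libraries, and no value without an effect was computed for them. A chance difference between the 5 GSK and the 5 MI hearts therefore stays open. A smaller share of infarcted tissue would move lists from MI (1) toward Sham (0). It need not place them at the same point, because tissue mixes in FPKM while positions were taken on means of log2(FPKM + 1). Unequal positions by themselves therefore do not test it. Of the 12 lists examined, neutrophils lay lowest, at 0.332 ± 0.362 (SD, n = 5). Ion handling lay at 0.449 ± 0.286, macrophages at 0.590 ± 0.273, oxidative phosphorylation at 0.849 ± 0.444 and cell cycle at 0.928 ± 0.184. The interferon response lay highest, at 1.64 ± 0.599, beyond MI. For cell cycle against macrophage genes, the single pair tested, the exact two-sided permutation p was 0.357, and on this scale the interferon list has an SD of 1.47 among MI libraries, so infarct share and treatment cannot be told apart with 5 libraries of this spread.

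A hypothesis set in advance was that the EZH2 inhibitor may release silent Polycomb target genes. Of 87 listed targets, 72 were left out of the test for low values, and their summed FPKM was 5.26 ± 1.10 in Sham, 7.74 ± 1.78 in MI and 5.86 ± 1.57 in GSK (SD, n = 5; exact two-sided permutation p = 0.103 for GSK against MI). By the bound set in advance, a p of at least 0.05 with a GSK mean not above that of MI argues against the hypothesis. That bound was too weak, because a p past 0.05 does not show that values did not differ and the sums rest on 278 to 766 fragments per library, so the hypothesis stays open. Of the 72, the mean was higher in GSK than in MI for 24 and lower for 37.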
